A study of Mus musculus with 5 samples.

How the data were processed

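Binding of 2 transcription factors was measured by ChIP-seq, in which DNA bound by a protein is recovered with an antibody and sequenced, in motor neuron progenitors made from mouse embryonic stem cells. The cells were Ainv15 lines, in which doxycycline switches on a factor carrying an epitope tag, a short peptide that a standard antibody recognises. Per the labels' protocols, embryoid bodies were patterned from day 2 with 1 µM retinoic acid and 0.5 µM of a hedgehog agonist, doxycycline was used at 3 µg/ml, cells were fixed in 1% formaldehyde and chromatin was sheared to about 500 bp. There were 5 samples from 6 libraries, and 4 of the samples had a list of binding events. A mock ChIP with anti-V5 in uninduced cells was the remaining sample and was not analysed here.

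Reads were aligned with Bowtie 0.12.5 to the mouse build mm9, per the submitters' processing notes. Events were named GPS_PEAK in the deposited interval lists; the version, settings and control library of the event caller are not given in the sources used here. Per the labels and the design text, each list came from 1 library, except that of V5-tagged Hoxc9, which was 1 list for 2 libraries. The event tables hold estimated counts of IP and control reads per event, which need not be whole, per the file headers and the values. They also hold the deposited fold of IP over control, listed as 9999.9 where control reads were 0, and the −log10 of p and of q for each event as deposited by the authors. A pair of further score columns deposited by the authors was not used. IP reads, fold and p are the authors' values for an event and were used to describe, rank or filter events within a list. Library totals were not used here, so sequencing depth is unknown and IP reads were not compared as levels between lists.

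Each event is a single base in mm9, printed as the event tables give it. The interval lists start at the same number, so a position can be off by 1 bp under the other counting convention. Events on the 19 autosomes and X were used, and 22 events on unplaced contigs were left out. A site was called shared when the other list held a site within 200 bp. Chance sharing was taken from 1000 circular shifts of the other list along each chromosome by at least 100 kb, within the span of sites of all 4 lists. The one-sided permutation p cannot go below 0.001, and Benjamini-Hochberg adjustment ran over 36 such tests. The shifts spread sites over the whole span and do not follow open chromatin, so sharing with lists of the other factor was given as a second comparison. It can include regions that both factors bind. Sharing with the same and the other factor was compared at the same sites with an exact two-sided McNemar test, 16 tests in all. Percentages carry Wilson 95% intervals, which cover counting error only, since neighbouring sites are not independent.

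Correlations of log2 IP reads ran across mutually nearest sites within 200 bp, with two-sided permutation tests of 100000 resamples (smallest p 1e-05). Intervals for Spearman's rho came from 1000 resamplings of whole chromosomes. There were no replicate lists, so every p compares these lists and not the conditions. Sites were named by a rule: for each pair of lists of 1 factor, the 10 shared sites whose worse rank by IP reads was best, and for each list the 5 sites with most IP reads and no site of the other list within 1 kb. The tests in the report, this rule and the following alternatives were set before the data were examined: other sharing distances (100, 500 and 1000 bp), overlap of the deposited intervals, stricter IP read and fold minimums, merged neighbours, other numbers of top sites, and ranking by p. Lists of equal length, lists without sites rich in control reads, and the comparison of the Olig2 with the Hoxc9 pair of lists, with its alternatives, were added after seeing the data, as were the tests that the closing section names as such.

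The sharing test was tested on simulated lists of the real lengths, with sites placed evenly at random over the chromosome spans. Real sites cluster, so this checks the recovery of planted sharing and not the chance level for these lists. With 20% of 15697 sites planted as shared, 20.1% were recovered for the Olig2 pair, and with 20% of 11065 sites, 20.7% for the Hoxc9 pair, before subtracting chance. Planned tests of motif content, of gene lists near sites and of location in genes needed the mm9 sequence and annotation and were not run, so sites are named by position without gene names. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.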

Results

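Genomic binding sites of Olig2 and Hoxc9 were listed in motor neuron progenitors derived from mouse embryonic stem cells. Olig2 is a basic helix-loop-helix factor of motor neuron progenitors, and Hoxc9 is a homeodomain factor of the thoracic spinal cord. For Olig2, 1 list came from day 4 cells without doxycycline and an antibody to the native protein, and 1 from day 4 cells of the same line with doxycycline and an antibody to the V5 tag. For Hoxc9, the lists came from day 5 cells with doxycycline, with the V5 tag in 1 line and the Flag tag in another. The native Olig2 list held 15700 events, the V5 Olig2 list 11071, the V5 Hoxc9 list 11070 and the Flag Hoxc9 list 49288. Median IP reads per event were 31.6, 47.4, 52.7 and 59, and median control reads were 1, 3.1, 2.9 and 2.4, in the same order. There was 1 list per condition and no replicate, so no difference below has a replicate check.

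Olig2 was mapped with 2 antibodies to ask whether a tag on an induced factor gives the sites that an antibody to the native protein gives. Nearly all of the strongest sites were found in both lists. The site at 71222033 on chromosome 17 had the most IP reads in the native list (1152) and lay 12 bp from the second-ranked V5 site (1165 IP reads). Of the 1000 native sites with most IP reads, 99.2% had a V5 site within 200 bp (Wilson 95% interval 98.4 to 99.6), and of the 1000 top V5 sites 99.6% had a native site (996 of 1000). Over whole lists, 56.7% of native sites (8905 of 15697; 56.0 to 57.5) and 78.1% of V5 sites (8647 of 11067; 77.4 to 78.9) were shared.

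The other shared Olig2 sites at the top were spread over several chromosomes. The site at 128758708 on chromosome 1 had 876.6 native IP reads, and its V5 partner 10 bp away ranked first in its list with 1232.5. On chromosome 16, the native site at 29642618 had 1004 IP reads and its V5 partner 817. A pair of neighbouring sites on chromosome 13, at 64122341 and 64122441, was resolved in both lists, with 806.2 and 778.8 native IP reads and 690 and 791 V5 IP reads. The sites at 55447590 on chromosome 11, 4074472 on chromosome 2, 45533431 on chromosome 19, 127972454 on chromosome 6 and 125566524 on chromosome 8 completed the 10, with native ranks from 3 to 14. Their V5 partners lay within 21 bp.

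Sites found in 1 Olig2 list alone were weaker. The strongest native site with no V5 site within 1 kb, at 86521194 on chromosome 10, had 152 IP reads and ranked 585. The next were at 62683288 on chromosome 1 (139 IP reads) and 90355819 on chromosome 8 (135.9 IP reads). The strongest V5 site with no native site within 1 kb, at 181408363 on chromosome 2, had 160 IP reads and ranked 689. It was followed by 122852571 on chromosome 14 (148.6 IP reads). Median IP reads were 43.5 at shared and 24 at unshared native sites, and 54.1 and 32.5 at V5 sites. Sharing fell from 98.7% in the 10% of native sites with most IP reads to 29.0% in the 10% with fewest, and from 99.5% to 39.1% for V5 sites.

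**Figure D1:**
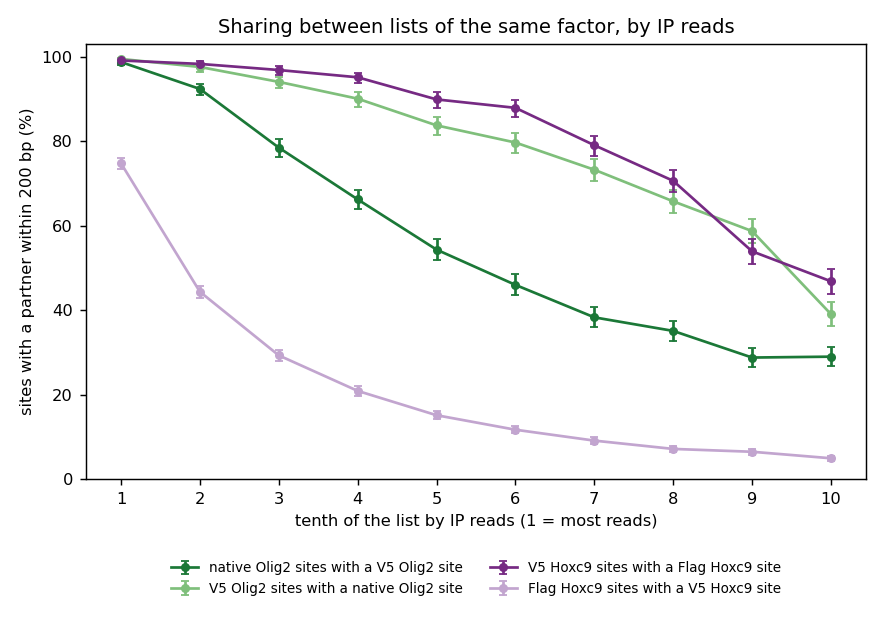
Percent of sites with a site of the same factor's other list within 200 bp (vertical axis), in 10 equal parts of each list ordered by IP reads (horizontal axis, 1 = most reads); colours are lists and bars Wilson 95% intervals. From the part with most to the part with fewest IP reads, sharing falls in all 4 lists, from 98.7% to 29.0% for native Olig2 and from 74.8% to 4.95% for Flag Hoxc9.

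At the 8356 one-to-one shared Olig2 sites, positions differed by a median of 13 bp, and 93.6% lay within 50 bp. IP reads in the lists were correlated across these sites (Spearman's rho 0.702, 95% interval 0.691 to 0.714; Pearson's r 0.759 on log2 reads). The permutation p was 1e-05 for each, the smallest these permutations can give, and 1e-05 after adjustment over 2 correlations. Leaving out the top 10 percent of either list gave a rho of 0.530. Sites are not independent replicates. Shifted lists shared 0.174% of native sites on average and at most 0.312%, so p was 0.001, the smallest the shifts can give, and 0.001 after adjustment. The lists differed in induction as well as in antibody.

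Hoxc9 was mapped with the V5 and the Flag tag to compare 2 independent tags on 1 factor. Most V5 sites were found with Flag, while most Flag sites were absent from the V5 list. The Flag list was 4.45 times as long. It held a site within 200 bp of 81.8% of V5 sites (9046 of 11065; 81.0 to 82.5), and the V5 list one near 22.4% of Flag sites (11034 of 49278; 22.0 to 22.8). Of the 1000 sites with most IP reads, 99.1% of V5 sites were in the Flag list (98.3 to 99.5) and 93% of Flag sites in the V5 list (91.2 to 94.4).

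The site at 103135814 on chromosome 15 had 1597 IP reads in the V5 list, and its Flag partner 13 bp away ranked first with 4764. Further shared sites at the top of both lists lay at 39615901 on chromosome 13 (732 V5 and 2350 Flag IP reads), 117003575 on chromosome 4 (946 and 2271.5) and 73149979 on chromosome 4 (696.8 and 2352.1). At 117357338 on chromosome 6 the control reads were listed at 0 in both lists, beside 681 V5 and 1970.6 Flag IP reads. The rest of the 10 were at 102845099 on chromosome 15, 27704719 on chromosome 8, 96168369 on chromosome 11, 74831760 on chromosome 12 and 129428100 on chromosome 1. Their V5 ranks ran from 5 to 16, and their Flag partners lay within 15 bp.

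The V5 sites with most IP reads and no Flag site within 1 kb were a pair near the listed start of chromosome 9. The site at 3000454 ranked first in the V5 list with 1626.8 IP reads and 254 control reads, and that at 3001412 ranked 3 with 1472 IP reads and 91.4 control reads. The next such V5 site, at 36060618 on chromosome 1, ranked 713 with 154 IP reads and 8.8 control reads. It was followed by 115751429 on chromosome 5 (150 IP and 35.4 control reads, fold 4.2). The last of the 5 was 84973039 on chromosome 12 (146 IP and 44.2 control reads, fold 3.3). The V5 Hoxc9 list had a median of 2.9 control reads and a median fold of 13.1. Whether V5 sites without a Flag site are regions rich in control reads was not tested. In the Flag list, the site at 108810723 on the X chromosome ranked 18 with 1686 IP reads and had no V5 site within 1 kb. The following ones were at 84416317 on chromosome 6 (945 IP reads), 46806537 on chromosome 6 (928.4), 98945407 on chromosome 5 (918) and 27556884 on chromosome 8 (892).

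Median IP reads were 59.3 at shared and 32 at unshared V5 sites, and 131 and 51 at Flag sites. At the 8933 one-to-one shared Hoxc9 sites, positions differed by a median of 21 bp, and 85.2% lay within 50 bp. IP reads were correlated across these sites (rho 0.605, 95% interval 0.592 to 0.620; r 0.644 on log2 reads), with a permutation p of 1e-05 for each and 1e-05 after adjustment. Without the top 10 percent of either list rho was 0.378. Shifts gave at most 1.02% of V5 sites shared and 0.233% of Flag sites, with p 0.001 and 0.001 after adjustment. With the Flag list held to the V5 list's length, 50.1% of V5 and 56.5% of Flag sites were shared, so the whole-list percentages depend on list length. The lists came from different lines.

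**Figure D2:**
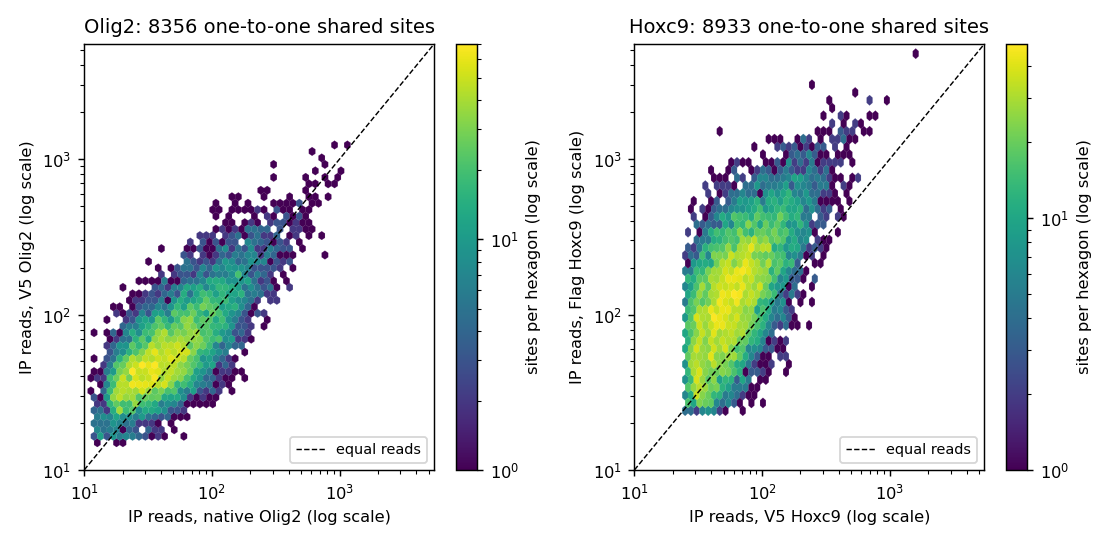
IP reads at one-to-one shared sites in the lists of Olig2 (left: native against V5) and Hoxc9 (right: V5 against Flag), on log axes; hexagon colour gives the number of sites and the dashed line marks equal reads. IP reads rise together in both panels, with rho 0.702 over 8356 sites and 0.605 over 8933.

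Lists of the 2 factors were compared to measure how many sites lists of different factors from these cells share. Such sharing can include regions that both factors bind. The lists of the factors also differed in day (4 and 5) and line. Among the top 1000 sites of each list, fewer were shared across factors than within a factor. Of the 1000 native Olig2 sites with most IP reads, 65.6% were among the top 1000 V5 Olig2 sites (62.6 to 68.5), 7.3% among the top V5 Hoxc9 sites and 3.7% among the top Flag Hoxc9 sites. For the top V5 Hoxc9 sites, 53.1% were among the top Flag Hoxc9 sites (531 of 1000), 6.6% among the top native Olig2 sites and 5.3% among the top V5 Olig2 sites.

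For the top V5 Olig2 sites, 66.1% were among the top native sites and 5.7% among the top V5 Hoxc9 sites. For the top Flag Hoxc9 sites, 55.7% were among the top V5 Hoxc9 sites and 3.6% among the top native Olig2 sites. Among the comparisons of top 1000 sites, the largest p was at the V5 Hoxc9 sites, where 500 were shared with Flag Hoxc9 alone and 35 with native Olig2 alone (exact McNemar p 1.84e-106, adjusted 1.84e-106). Set against whole lists, sharing across factors was higher: 46.7% of the top native and 44.4% of the top V5 Olig2 sites had a Flag Hoxc9 site, and 35.8% of the top V5 Hoxc9 sites had a native Olig2 site. In whole lists, 29.8% of native Olig2 sites had a Flag Hoxc9 site and 12.6% a V5 Hoxc9 site, while 16.5% of V5 Hoxc9 sites had a native Olig2 site. At equal list length the first was 15.7% and the second 13.7%, and with a fold of 10 or more the second was 6.52%. With only sites at or below their list's median of control reads, the percentages were 14.9%, 5.75% and 7.93%. This left fewer sites in each list, and the means of the shifts fell too. They went from 0.733%, 0.176% and 0.242% to 0.369%, 0.0889% and 0.126%. Each of the 8 directed comparisons across factors lay above its shifts (p 0.001, adjusted 0.001).

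**Figure D3:**
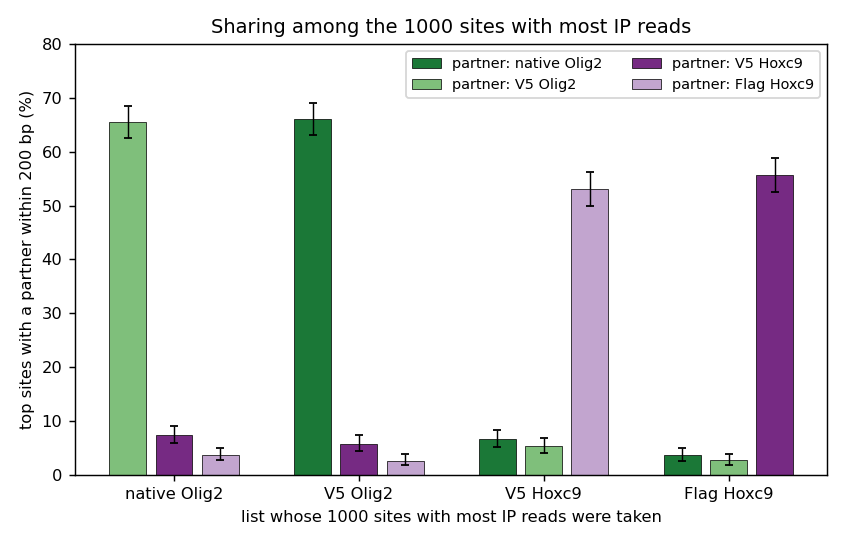
Percent of the 1000 sites with most IP reads of each list (groups of bars) that have a site among the top 1000 of another list within 200 bp; bar colour names the other list and error bars are Wilson 95% intervals. Sharing within a factor lies between 53.1% and 66.1%, and across factors between 2.6% and 7.3%.

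Chaining sites within 200 bp over the 4 lists gave 58192 regions. Of these, 5427 held sites of both Olig2 lists alone, 6825 of both Hoxc9 lists alone, 32586 of the Flag Hoxc9 list alone and 971 of all 4 lists. The strongest of the 971, by worst rank, spanned 113301085 to 113301295 on chromosome 11 and held at most 486.4 native Olig2, 356 V5 Olig2, 238 V5 Hoxc9 and 616 Flag Hoxc9 IP reads. The next spanned 45533431 to 45533460 on chromosome 19, the position of 1 of the top 10 Olig2 sites above, with 214 V5 Hoxc9 and 591.1 Flag Hoxc9 IP reads. The third spanned 127801427 to 127801478 on chromosome 8, where the V5 Hoxc9 site had 53 control reads.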

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

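The tests that set V5 sites against sites of the partner list alone, the test of fold at Flag sites, and the comparison of the Olig2 pair of lists with the Hoxc9 pair with all its alternatives, were chosen after the results were seen.

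The top 1000 sites were shared one-to-one more often between the Olig2 lists than between the Hoxc9 lists, and this difference between the pairs of lists brought the result here. The difference was 12.2 percentage points (63.6% against 51.4%). With 1 pair of lists per factor, it describes these 4 lists and no difference between factors could be tested. It was 11.4 points over 500 top sites and 15.5 over 2000. At equal list length, 67.5% of native and 67.1% of V5 Olig2 sites were shared, beside 50.1% of V5 and 56.5% of Flag Hoxc9 sites. The gap between the pairs remained, which argues against list length alone as its cause. In whole partner lists the top sites were closer, 99.2% and 99.6% for Olig2 beside 99.1% (V5) and 93% (Flag) for Hoxc9. The Olig2 lists shared a line and differed in induction, while the Hoxc9 lists came from different lines and 1 of them from 2 libraries. Both Olig2 lists were from day 4 and both Hoxc9 lists from day 5, and sequencing depth is unknown. Factor, day, line, depth and library number therefore cannot be separated, and none of them was tested as the cause. The other result was 22 events on unplaced contigs, which the comparisons did not use. They had more IP than control reads, as did the other listed events, whose lowest fold was 3.1, and the strongest was in the Flag Hoxc9 list with 480 IP and 10.4 control reads.

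The Flag Hoxc9 list was 4.45 times as long as the V5 Hoxc9 list. A candidate explanation is that weaker sites passed the authors' threshold only with Flag: sharing fell in every step from 74.8% in the 10% of Flag sites with most IP reads to 4.95% in the 10% with fewest. Regions rich in control reads were another candidate, and the values did not decide it. Median control reads were 2.4 at the 38244 Flag sites without a V5 site and 2.3 at Flag sites with one. The difference of 0.1 had the direction set beforehand for this cause, but its 95% interval by chromosome ran from -0.1 to 0.3. A fold of 10 or more was seen at 76.6% of the sites without a V5 site (Wilson 95% interval 76.2 to 77.0). Over all Flag sites, most of which lack a V5 site, the share was higher (39723 of 49278). It was thus higher still at Flag sites with a V5 site, a wider gap than this contrast shows. With median control reads of 2.4, the test of fold could hardly have gone otherwise, because every listed Flag event had at least 24 IP reads. The rule set beforehand for weaker sites was met, as 74.8% was no more than 10 points below the 81.8% of V5 sites with a Flag site. Not all of the 10% of Flag sites with most IP reads had a V5 site. With depth unknown, whether weak sites are the whole account cannot be told from this. Of the 10% of V5 Hoxc9 sites with most IP reads, 99.1% had a site in the longer Flag list. Among the top 1000 Flag sites, 93% had a V5 site, and the X chromosome site at 108810723, ranked 18, had none. Sharing fell with IP reads in all 4 lists, so the fall alone does not single out the threshold. A difference between the 2 lines in bound Hoxc9 stays open and untested.

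Whether V5 sites without a partner site hold background of the V5 antibody was tested, and the values were mixed. Of 2420 V5 Olig2 sites with no native site, 127 had a V5 Hoxc9 site and 70 a site among as many top Flag Hoxc9 sites, a difference of 2.36 points (exact McNemar p 5.46e-08), but 301 had a site in the whole, longer Flag list. Of 2019 V5 Hoxc9 sites with no Flag site, 109 had a V5 Olig2 site and 88 a top native site, a difference of 1.04 points (p 0.0125), but 117 had a site in the whole native list. With lists of equal length, the lean toward the other V5 list was stronger than at sites of the partner lists alone, with odds ratios of 2.86 (exact Fisher p 5e-06) and 3.71 (p 8.23e-07). The shares themselves went both ways, with a V5 Hoxc9 site at 5.25% of the 2420 sites and 10.7% of native sites without a V5 Olig2 site, and a V5 Olig2 site at 5.40% of the 2019 sites and 4.91% of Flag sites without a V5 Hoxc9 site, so how much of the set it may account for stays open, as does induction, which separates the native list from the other 3 and was not tested.

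Sites shared between Olig2 and Hoxc9 lists were more frequent than in shifted lists. The values argue against regions rich in control reads as the whole cause: with only sites at or below their list's median of control reads, sharing across factors was between 3.35% and 14.9%, at least 34.4 times the mean of the shifts and 21.3 times their highest. Chromatin open to any factor, and binding of both factors at the same regions, may each contribute and were not tested, since the shifts do not follow open chromatin.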

How the results depend on the processing

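The alternatives of equal list length, of sites poor in control reads and all those for the difference between the Olig2 and the Hoxc9 pair of lists, with that result itself, were chosen after seeing the data. All 19 results kept their direction in the 158 alternatives run. Each shift p was 0.00498, the smallest those shifts can give, however far sharing fell, so the p-values say little about stability and the sizes matter. Overlap of the deposited 1 bp intervals asks for identical positions and gave 1.11% of native Olig2 and 0.254% of Flag Hoxc9 sites shared with their partner list, which follows from its construction. Equal list length moved Hoxc9 sharing to 50.1% (V5) and 56.5% (Flag), native Olig2 sites in the Flag list to 15.7%, V5 Olig2 sites in it to 10.6%, and Flag sites to 16.0% in the native and 10.7% in the V5 Olig2 list. A fold of 10 or more left 6.52% of native and 6.85% of V5 Olig2 sites in the V5 Hoxc9 list. Without control-rich sites the 8 percentages across factors fell to between 3.35% and 14.9%, with fewer sites in each list by construction. Motif, gene list and location alternatives were not run, as these tests needed mm9. Unknown depth limits what absence from a list shows: a site under a list's threshold is not a site without binding. No paired analysis was possible because each condition had 1 list.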

Other observations

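Each test in this part was chosen after the values were seen.

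Binding was dense in a few windows of 100 kb. The window from 52100001 to 52200000 on chromosome 6 held 25 V5 Hoxc9 and 42 Flag Hoxc9 sites, the most of any window in both lists, beside 14 native and 10 V5 Olig2 sites. The next V5 Hoxc9 windows started at 96100001 on chromosome 11 (13 sites), 102800001 on chromosome 15 (12 sites) and 74500001 on chromosome 2 (12 sites). Both Olig2 lists were densest from 123000001 to 123100000 on chromosome 8, with 20 native and 14 V5 sites, followed by the window at 76100001 on chromosome 11 with 16 and 11. The Flag Hoxc9 window at 115300001 on chromosome 2 held 29 Flag sites and 8 V5 Hoxc9 sites, and neither Olig2 list had a site there.

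The 4 densest V5 Hoxc9 windows may lie over the Hox gene clusters, which are on chromosomes 2, 6, 11 and 15 in the mouse. Each of these 4 chromosomes held 1 of the 4 windows. In the Flag Hoxc9 list, the windows on chromosomes 6 and 11 were again among the 4 densest, and the others were different windows, at 115300001 on chromosome 2 and 55100001 on chromosome 18. The hypothesis stays open, because it was formed from these windows and no mm9 annotation was used here to place the clusters.

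The control columns may come from 1 control library scaled to each list. At 293 sites within 10 bp of each other and with over 3 control reads in both Olig2 lists, the native to V5 ratio of control reads had a median of 0.333 and an interquartile range of 2.99% of that median. Independent counts of so few reads would spread more widely. The ratio of V5 to Flag Hoxc9 control reads was 1.42 (interquartile range 1.40 to 1.44, 1362 sites). Ratios to V5 Hoxc9 were 0.117 for native Olig2 (0.115 to 0.117, 15 sites) and 0.351 for V5 Olig2 (0.326 to 0.354, 84 sites). Ratios to Flag Hoxc9 were wider, 0.173 for native Olig2 (0.166 to 0.295, 39 sites) and 0.5 for V5 Olig2 (0.494 to 0.597, 270 sites). Their lower quartiles lay close to the medians, and only the upper quartiles lay well above. A constant factor thus does not describe every ratio of the Olig2 lists to the Flag list. Shared control reads would make the fold and p values of the 4 lists partly dependent on each other.

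Sites on the X chromosome were few. They made up 1.50% of native Olig2, 1.57% of V5 Olig2, 0.904% of V5 Hoxc9 and 1.64% of Flag Hoxc9 sites, while X made up 6.28% of the span of all sites. No cause was tested.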
